A study of Aspergillus niger with 9 samples.

How the data were processed

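RNA was measured in vegetative mycelium of the filamentous fungus Aspergillus niger, in 9 libraries from 3 strains with 3 biological replicates each: the reference strain MA234.1, the deletion strain ΔaslA and the deletion strain ΔaslB. Per the labels' protocols, the strains were grown in shaken liquid medium, and the protocol names a 16 h culture on 25 mM glucose in a rich medium (casamino acids at 0.2%, yeast extract at 0.5%) and a 4 h culture on 25 mM xylose. The labels do not say which of these cultures a given library came from. Libraries were made with a stranded poly(A) kit and read as pairs of 50 bp.

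Per the submitters' processing notes, HISAT2 2.2.1, Cuffdiff, Subread and featureCounts were used; their roles, settings and strand mode, and the genome build, are not given in the sources used here. The authors deposited whole-number read counts for 11187 genes in each library, without normalization. The authors' deposited table holds 1 FPKM value per strain, in which replicates are already combined. It also gives a log2 ratio of FPKM values for each pair of strains, and a q-value for each gene and pair. Recomputing the deposited log2 ratios from FPKM + 1 and the deposited calls from the table's own columns gave 0 genes that departed from a rule of an absolute log2 ratio of at least 2, a q-value under 0.05 and at least 10 FPKM in the higher strain. Gene names, protein families and positions were taken from the same table. A symbol is that of the closest SwissProt protein, often of another species, and 8074 genes had such a match. Where 2 genes share a symbol, as for xlnR and brlA, which of them is the regulator itself was not tested. The reference table of gene symbols uses identifiers of another strain and was not used here. No gene was matched to the name aslA or aslB, so the deleted genes were not checked by name.

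Differential expression was tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's filter on low counts by group, and 1 fit of all 9 libraries with the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left 9568 genes; 193 genes had no count in any library. Expression is given as edgeR's CPM, a gene's count scaled by the library's total count, after TMM scaling, as mean ± SD. The 3 comparisons were ΔaslA against MA234.1, ΔaslB against MA234.1 and ΔaslA against ΔaslB, the last being also the test of whether the effects of the deletions differ. The 33 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 3 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01, and again with an estimated correlation. Categories of the deposited annotation and gene ontology terms of 10 to 500 genes were tested the same way and were chosen after the data had been seen.

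Genes were named by a fixed rule. For each comparison it took the 12 largest rises and 12 largest falls among called genes whose replicates did not overlap between groups, whose higher group averaged at least 5 CPM and which had a symbol or functional description. It added 2 genes without such a description, or described as uncharacterized, in each direction, up to 4 called members of each list, and the regulators flbA, brlA, xlnR and amyR; no gene was matched to amyR. The rule named genes in the first comparison and, since the main edgeR fit called no gene in the others, only the regulators there. Where every library of a group had 0 counts, a fold was computed against a floor of 3 counts over the group, and such floors cover counting error only.

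Library totals ran from 11321882 to 19110786 counts, so that 3 counts corresponded to between 0.157 and 0.265 CPM per library. Replicate pairs were compared by a chi-square test of their counts, which gave between 2.36 and 643 per degree of freedom; no pair agreed within sampling noise, and all 9 libraries were kept. The test was run on simulated data with 200 changed genes. For ΔaslA against MA234.1 it recovered 67% of the 4-fold and 97% of the 16-fold changes among 9478 genes. For ΔaslB against MA234.1 it recovered 57% and 92% among 9461 genes, and for ΔaslA against ΔaslB 61% and 94% among 9454 genes. With only 200 genes changed, these shares do not describe a group whose libraries lie far apart, as those of ΔaslB did. They therefore cannot show that a lack of calls in the ΔaslB comparisons is a lack of change.

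Alternatives were other size factors, total counts alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, only the 6 libraries compared, the replicate number as a block, a fold threshold, and each library left out in turn. Leaving out a library of the group that a comparison does not use, and testing lists in the 6 libraries compared, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.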

Results

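Poly(A) RNA of A. niger mycelium was sequenced from MA234.1, ΔaslA and ΔaslB, with 3 libraries per strain. The series concerns transcription factors acting downstream of FlbA, a regulator of G protein signalling that controls development and secretion in aspergilli. The comparisons ask which transcripts differ when aslA or aslB is deleted. Total counts were 11321882, 13493729 and 13177156 for MA234.1 replicates 1 to 3, 13954909, 19110786 and 13274592 for ΔaslA, and 13199221, 15068386 and 12223991 for ΔaslB.

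The 3 libraries of MA234.1 correlated with each other at r = 0.984 to 0.991 across genes, and those of ΔaslA at 0.971 to 0.991. The libraries labelled ΔaslB correlated at only 0.799 to 0.943. The library labelled ΔaslB replicate 2 correlated at 0.970 to 0.978 with the MA234.1 libraries and at 0.777 to 0.798 with those of ΔaslA. The library labelled ΔaslB replicate 3 correlated at 0.967 to 0.984 with ΔaslA and at 0.772 to 0.777 with MA234.1, and replicate 1 at 0.922 to 0.941 with ΔaslA. Genes are not independent replicates, and these correlations are across genes. The median SD of log2 CPM between replicates was 0.125 in MA234.1, 0.254 in ΔaslA and 0.619 in ΔaslB.

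**Figure D1:**
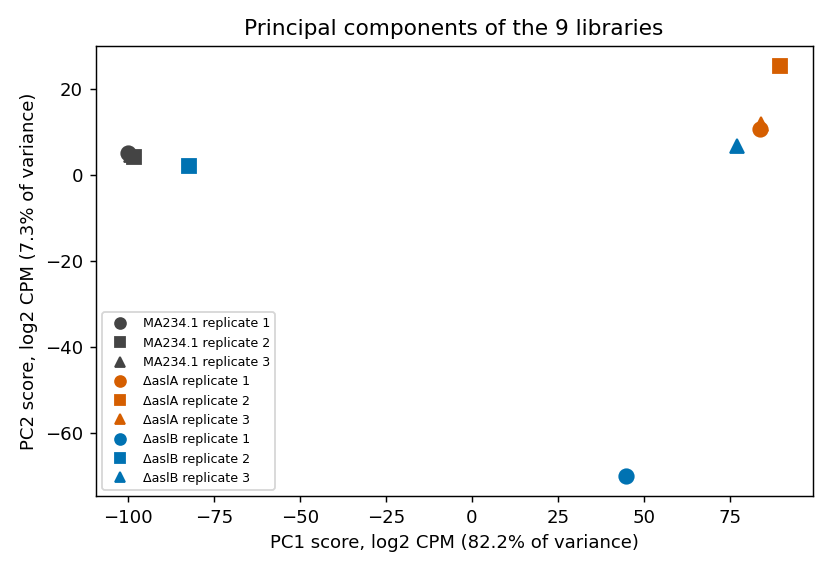
Scores of the 9 libraries on the first and second principal components of log2 CPM, which hold 82.2% and 7.3% of the variance; colour marks the labelled strain and shape the replicate. MA234.1 lies between -99.9 and -98.2 on the first axis and ΔaslA between 83.7 and 89.6, while the ΔaslB libraries lie at 44.8, -82.3 and 77.1.

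Between ΔaslA and MA234.1, camera placed the lists of ribosomal proteins, oxidative phosphorylation and chaperones higher in ΔaslA, and 11 lists, among them β-oxidation, sugar transporters and secreted proteases, lower. Every one of these calls was lost with an estimated correlation (adjusted p = 0.509 or more with an estimated correlation). All 84 measured genes of the ribosomal list rose (median log2 fold change 2.53). ACL1 (ATCC64974_87430, contig 16, 191968 to 194156), a subunit of the ATP-citrate synthase that supplies cytosolic acetyl-CoA, rose from 16.9 ± 0.591 to 863 ± 99.0 CPM (SD, n = 3 each). In the opposite direction the arabinofuranosidase gene abfB (ATCC64974_30860, contig 4, 1301755 to 1303255) fell from 1300 ± 69.6 to 0.719 ± 0.343 CPM, and the cell wall mannoprotein gene MP1 (ATCC64974_1880) from 5600 ± 294 to 3.87 ± 0.654 CPM. Of 9568 genes, edgeR called 4638, of which 2251 were higher and 2387 lower in ΔaslA; 1754 and 2093 of these changed by at least 1 on the log2 scale. The 3 libraries of each strain did not overlap in 74.7% of all 9568 genes, where chance gives 10%. Without MA234.1 replicate 2 and replicate 3 the count was 3054 and 3008.

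Among the largest rises were RPAP3 (ATCC64974_13770), closest to an RNA polymerase II-associated protein, at 0.0497 ± 0.0862 against 5.71 ± 0.784 CPM, and several genes of ribosome assembly and translation. The ribosomal list (84 of 84 called over all genes, 84 adjusted over the list alone) was called by camera (adjusted p = 1.46e-18), but not with an estimated correlation (adjusted p = 0.509 with an estimated correlation). Among its largest rises were members that are assembly or splicing factors and not structural ribosomal proteins: snu13 (ATCC64974_51320), a ribonucleoprotein-associated protein, changed by 4.47, and the assembly factors MAK16 (ATCC64974_31500) and mrt4 (ATCC64974_4100) by 3.99 and 3.84. Among single genes, the pre-60S remodelling ATPase midasin, MDN1 (ATCC64974_62330), rose from 2.18 ± 0.898 to 92.5 ± 2.14 CPM (log2 fold change 5.40, SE 1.11, edgeR adjusted p = 0.00867). The rRNA helicase gene has1 (ATCC64974_16060) changed by 5.36 and the rRNA processing gene EBP2 (ATCC64974_21330) by 4.90. The translation initiation helicase gene tif1 (ATCC64974_53390) rose from 43.2 ± 3.63 to 1250 ± 194 CPM. Chaperones bound to the ribosome rose as well: SSB1 (ATCC64974_66140) from 46.9 ± 1.01 to 1910 ± 455 CPM and SSZ1 (ATCC64974_47840) from 10.4 ± 2.42 to 301 ± 1.41 CPM. Of 49 heat shock proteins and chaperones 21 rose and 3 fell (21 and 3 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.509 with an estimated correlation). In oxidative phosphorylation 24 of 54 genes rose and 0 fell (20 and 0 adjusted over the list alone), with camera adjusted p = 1.19e-06 and adjusted p = 0.533 with an estimated correlation. Among them atp9 (ATCC64974_85290) of the mitochondrial ATP synthase rose from 662 ± 28.7 to 3770 ± 449 CPM.

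Of 16 xylanolytic, cellulolytic and xylose catabolic genes 10 fell and 0 rose (12 and 1 adjusted over the list alone; median -2.11; camera adjusted p = 0.00382; adjusted p = 0.532 with an estimated correlation). Alongside abfB, the arabinofuranosidase gene abfA (ATCC64974_23190) fell from 496 ± 19.5 to 3.66 ± 1.23 CPM, and the xylosidase gene xlnD (ATCC64974_15350) from 45.8 ± 0.902 to 2.55 ± 0.970 CPM. The arabinitol dehydrogenase gene ladA (ATCC64974_14710) fell from 104 ± 0.765 to 4.85 ± 2.37 CPM. Of the 2 genes closest to xlnR, the transcriptional activator of this system, ATCC64974_28320 fell from 164 ± 7.61 to 34.6 ± 2.91 CPM (log2 fold change -2.24, SE 0.39, edgeR adjusted p = 0.00841) and ATCC64974_91960 from 26.4 ± 0.309 to 1.38 ± 0.550 CPM. Of 50 plant cell wall polysaccharide hydrolases, 7 of them also in the list before, 20 fell and 3 rose (19 and 3 adjusted over the list alone), including the exopolygalacturonase gene pgxB (ATCC64974_76140), from 57.9 ± 4.37 to 0.481 ± 0.177 CPM; camera gave adjusted p = 0.0128, and adjusted p = 0.533 with an estimated correlation. Of the starch list, which shares 5 genes with the list of cell wall synthesis, 12 of 24 genes fell and 7 rose (14 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.117). Glucoamylase (ATCC64974_75950), a main starch-degrading enzyme, fell from 3690 ± 31.7 to 61.3 ± 7.56 CPM, and acid alpha-amylase (ATCC64974_89550) from 374 ± 18.3 to 1.12 ± 0.448 CPM.

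Of 24 β-oxidation genes 21 fell and 1 rose (22 and 2 adjusted over the list alone; median -2.86; camera adjusted p = 2.2e-06; adjusted p = 0.509 with an estimated correlation). The carnitine acetyltransferase gene YAT1 (ATCC64974_102400) fell from 1150 ± 21.4 to 24.2 ± 3.55 CPM. The glyoxylate cycle genes acuE (malate synthase, ATCC64974_31190) and icl1 (isocitrate lyase, ATCC64974_15880) were among the most abundant transcripts of MA234.1, at 7280 ± 290 and 7310 ± 305 CPM, and stood at 34.3 ± 3.74 and 86.5 ± 2.91 CPM in ΔaslA. The gluconeogenic gene acuF (ATCC64974_88970) stood at 9870 ± 208 against 678 ± 48.6 CPM. Their calls (edgeR adjusted p = 0.0138, 0.0154 and 0.0156) were lost without ΔaslA replicate 1 or 2, and those of icl1 and acuF also without replicate 3. Over the 17 of 18 alternatives that gave them an adjusted p, that of acuE ran from 1.3e-08 to 0.0532. That of icl1 ran from 1.25e-08 to 0.0587 and that of acuF from 3.3e-08 to 0.0582. In the ΔaslB libraries acuE stood at 62.3, 6300 and 29.2 CPM, icl1 at 55.9, 5220 and 77.5, and acuF at 379, 6850 and 568. The fits that lost these calls estimate spread over the ΔaslB libraries too. With only the 6 libraries compared, 0 named results lost their call, but no library was left out of that fit. How far the ΔaslB spread accounts for the lost calls was not tested. The list of tricarboxylic acid and glyoxylate cycle genes, 20 of 48 lower and 10 higher (20 and 11 adjusted over the list alone), was not called (camera adjusted p = 0.147); its text match also took in leu2B (ATCC64974_86770) of leucine synthesis and OXCT1 (ATCC64974_97700) of ketone body use, which changed by -6.22 and -6.79.

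Of 190 sugar transporters 94 fell and 13 rose (98 and 16 adjusted over the list alone), and of 343 major facilitator transporters, 179 of which are also in the sugar transporter list, 161 fell and 26 rose (170 and 31 adjusted over the list alone). The quinate permease gene qutD (ATCC64974_110460) fell from 567 ± 35.0 to 0.528 ± 0.0627 CPM, and the peptide transporter gene ptr2 (ATCC64974_76060) from 1080 ± 22.4 to 4.28 ± 1.33 CPM. Camera did not call ABC transporters (16 of 60 lower, 12 higher; the same numbers adjusted over the list alone; adjusted p = 0.535), cation transport (20 of 55 lower, 7 higher; the same adjusted over the list alone; 0.0976) or iron uptake (4 of 22 lower, 5 higher; 4 and 4 adjusted over the list alone; 0.86). Among amino acid and peptide transporters 29 of 70 fell and 7 rose (30 and 7 adjusted over the list alone). Of 39 secreted proteases 22 fell and 2 rose (23 and 2 adjusted over the list alone), among them the aspartic protease gene pep1 (ATCC64974_3930), from 175 ± 12.4 to 6.02 ± 0.687 CPM, and the tripeptidyl-peptidase gene sed4 (ATCC64974_96730), from 545 ± 33.0 to 13.6 ± 2.23 CPM. Camera called sugar transporters (adjusted p = 1.25e-06), major facilitators (1.19e-06), amino acid transporters (0.00303) and proteases (0.00012), each with adjusted p = 0.509 with an estimated correlation. The same estimated value applied to cytochrome P450 enzymes (48 of 93 lower, 4 higher; 49 and 4 adjusted over the list alone), polyketide and related synthases (19 of 54 lower, 5 higher; 18 and 3), heterokaryon incompatibility and lytic proteins (16 of 40 lower, 2 higher; 15 and 2) and binuclear cluster transcription factors (144 of 354 lower, 18 higher; 142 and 18). With the preset correlation their adjusted p was 7.31e-06, 0.00683, 0.00033 and 3.07e-06. In all, 14 of 33 lists were called, 3 higher and 11 lower, and 0 with an estimated correlation. Median and test differed in sign for 2 lists that were not called, hydrophobins (median 0.08) and nitrate and ammonium assimilation (0.23), which camera placed lower.

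Developmental regulators went in both directions. abaA (ATCC64974_20070), a regulator of conidiophore development, rose from 1.43 ± 0.595 to 19 ± 2.44 CPM, and fluG (ATCC64974_2970), an early activator of conidiation, from 60.4 ± 4.85 to 327 ± 15.8 CPM. stuA (ATCC64974_38800) fell from 297 ± 2.00 to 74.9 ± 6.09 CPM. Of the 2 genes closest to brlA, ATCC64974_72370 fell from 39 ± 2.08 to 16.1 ± 3.82 CPM, while ATCC64974_15030 stood at 1.44 ± 0.448 and 0.936 ± 0.535 CPM (edgeR adjusted p = 0.355). flbA (ATCC64974_61450) stood at 22.2 ± 2.15 in MA234.1 and 24.8 ± 3.41 CPM in ΔaslA (log2 fold change 0.16, SE 0.26, edgeR adjusted p = 0.629). Over the 8 measured regulators, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.86). Among the largest falls were genes with no count in ΔaslA. ATCC64974_78720, closest to the bacterial dehydrogenase gene kduD, was at 93.0 ± 5.28 CPM in MA234.1 and at least 1410-fold lower in ΔaslA. Its call (edgeR adjusted p = 0.0312) was lost without any 1 of the 6 libraries of these strains. Its adjusted p ran from 2.46e-07 to 0.0798 over the 17 of 18 alternatives that gave one. In the ΔaslB libraries this gene stood at 0.144, 122 and 0 CPM, and these fits estimate its spread over those libraries too. The lost calls therefore do not show that MA234.1 and ΔaslA overlap. With only the 6 libraries compared, 0 named results lost their call, but no library was left out of that fit. How far the ΔaslB spread accounts for the lost calls of this gene was not tested. ATCC64974_99170, on contig 17, which has no SwissProt match and is in the list of CFEM and cell wall anchored proteins, was at 201 ± 10.5 CPM in MA234.1 and at least 3040-fold lower.

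**Figure D2:**
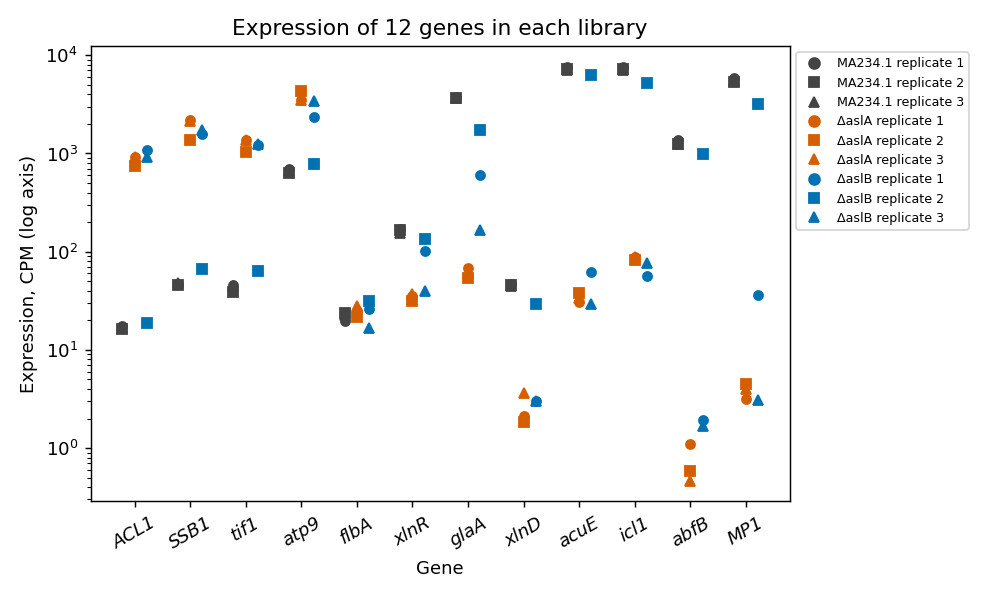
CPM of 12 genes in each library on a log axis; colour marks the labelled strain and shape the replicate. For abfB the MA234.1 mean was 1300 CPM and the ΔaslA mean 0.719 CPM, and ΔaslB replicates 1 to 3 stood at 1.95, 990 and 1.66 CPM.

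The authors' deposited table called 1504 genes between these strains, 634 higher and 870 lower in ΔaslA, under its stricter fold and FPKM rule.

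Between ΔaslB and MA234.1 no gene passed the main edgeR test, though DESeq2 called 1741 and edgeR with total counts alone 644. The libraries labelled ΔaslB lay far apart. Of the 4638 genes called for ΔaslA, 90.9% stood closer to the MA234.1 mean than to the ΔaslA mean in the library labelled ΔaslB replicate 2, against 19.4% in replicate 1 and 6.7% in replicate 3. ACL1 was at 1090, 18.9 and 915 CPM in ΔaslB replicates 1 to 3, against 16.9 ± 0.591 CPM in MA234.1. abfB was at 1.95, 990 and 1.66 CPM, acuE at 62.3, 6300 and 29.2 CPM, and MP1 at 36.5, 3210 and 3.08 CPM. The mean log2 CPM of the ribosomal list stood 2.29, 0.12 and 2.70 above MA234.1 in replicates 1 to 3, and that of the β-oxidation list at -2.18, -0.26 and -2.47.

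edgeR called 0 of 9568 genes in this comparison, with 2926 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0682. DESeq2 called 1741 genes, 1300 higher and 441 lower, limma-voom called 0 (3305 at an unadjusted p under 0.05), and edgeR with total counts alone called 644, 629 higher and 15 lower. Without ΔaslB replicate 2 edgeR called 5093 genes, 2557 higher and 2536 lower, and without replicate 3 it called 24, all higher. flbA stood at 25.9, 31.2 and 16.9 CPM in ΔaslB replicates 1 to 3, against 22.2 ± 2.15 CPM in MA234.1. The xlnR gene ATCC64974_28320 stood at 102, 135 and 39.6 CPM, against 164 ± 7.61 CPM, and the xlnR gene ATCC64974_91960 at 5.19, 15 and 3.16 against 26.4 ± 0.309 CPM. The brlA gene ATCC64974_72370 stood at 12.8, 25.6 and 16.5 CPM, against 39 ± 2.08 CPM (log2 fold change -1.09, SE 0.30, edgeR adjusted p = 0.0704), and the brlA gene ATCC64974_15030 at 1.23, 1.76 and 0.914 against 1.44 ± 0.448 CPM. The edgeR adjusted p of the other regulators was 0.692 for flbA, 0.169 and 0.0874 for the xlnR genes and 0.87 for ATCC64974_15030. Without ΔaslB replicate 2 edgeR called ATCC64974_72370 (adjusted p = 0.00139, over all alternatives 0.00139 to 0.232), ATCC64974_28320 (0.0136, over all alternatives 0.0136 to 0.32) and ATCC64974_91960 (0.000284, over all alternatives 0.000284 to 0.248), each lower in ΔaslB. With all 9 libraries DESeq2 also called ATCC64974_72370 (DESeq2 adjusted p = 0.0132) and ATCC64974_91960 (0.0168) lower, but not ATCC64974_28320. Adjusted over the list alone, 83 of 84 genes of the ribosomal list were higher, against 0 of 84 over all genes; camera gave adjusted p = 1.3e-19 (adjusted p = 0.58 with an estimated correlation). For β-oxidation 0 of 24 genes were called over all genes and 1 higher adjusted over the list alone, while the median was -1.50 and camera placed the list lower, with adjusted p = 1.4e-05 and adjusted p = 0.58 with an estimated correlation. Camera called 15 of 33 lists, 3 higher and 12 lower, and 0 with an estimated correlation. The authors' deposited table called 424 genes, 350 higher and 74 lower in ΔaslB.

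**Figure D3:**
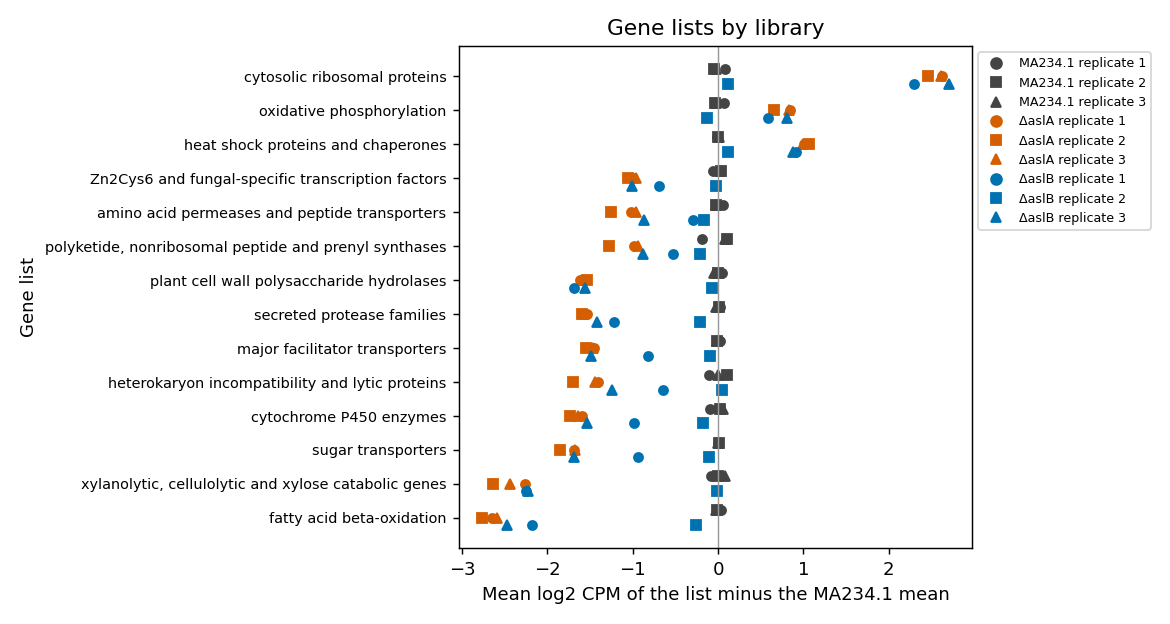
Mean log2 CPM of each of the 14 called gene lists in each library, minus the MA234.1 mean; colour marks the labelled strain and shape the replicate. The ribosomal list stands at 2.62, 2.46 and 2.61 in ΔaslA and at 2.29, 0.12 and 2.70 in ΔaslB.

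The ΔaslA and ΔaslB libraries were compared to ask whether the deletions differ in effect. No regulator was called by edgeR: the log2 fold change of ΔaslA over ΔaslB was 0.01 (SE 0.26, adjusted p = 0.993) for flbA, -1.42 (SE 0.38, adjusted p = 0.167) and -2.49 (SE 0.59, adjusted p = 0.157) for the xlnR genes ATCC64974_28320 and ATCC64974_91960, and -0.19 (SE 0.30, adjusted p = 0.758) and -0.49 (SE 0.53, adjusted p = 0.651) for the brlA genes ATCC64974_72370 and ATCC64974_15030. The next genes were chosen after their values were seen, from those named in the first comparison. ACL1 was at 863 ± 99.0 CPM in ΔaslA and at 1090, 18.9 and 915 CPM in ΔaslB replicates 1 to 3, and acuE at 34.3 ± 3.74 against 62.3, 6300 and 29.2 CPM. ptr2 was at 4.28 ± 1.33 CPM in ΔaslA and at 192, 778 and 9.81 CPM in ΔaslB replicates 1 to 3. Glucoamylase was at 61.3 ± 7.56 CPM in ΔaslA and at 602, 1730 and 168 CPM in those libraries, and the catalase-peroxidase gene katG (ATCC64974_21630) at 56.7 ± 10.2 against 679, 1370 and 89.5 CPM. edgeR called 0 of 9568 genes, with 1633 at an unadjusted p under 0.05 and a smallest adjusted p of 0.148. DESeq2 called 517, of which 35 were higher and 482 lower in ΔaslA, and limma-voom called 0 (1121 at an unadjusted p under 0.05). Without ΔaslB replicate 3 edgeR called 1245 genes, 202 higher and 1043 lower in ΔaslA, and without replicate 2 it called 52, 28 higher and 24 lower. The xlnR genes ATCC64974_28320 and ATCC64974_91960 were called lower in ΔaslA without ΔaslB replicate 3 (edgeR adjusted p = 0.00135 and 0.013, over all alternatives 0.00135 to 0.5 and 0.00143 to 0.5). With all 9 libraries DESeq2 also called both lower in ΔaslA (DESeq2 adjusted p = 0.0155 and 0.00143). Of the sugar transporters 0 were called over all genes, and 31 of 190 were lower adjusted over the list alone (camera adjusted p = 8.12e-07; adjusted p = 0.559 with an estimated correlation). Camera called 14 lists, 3 higher and 11 lower, and 0 with an estimated correlation. The authors' deposited table called 379 genes, 2 higher and 377 lower in ΔaslA.

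In the main edgeR fit no gene was called in both deletions against MA234.1 with the same sign, since ΔaslB gave 0 calls. DESeq2 gave 1668 such genes and edgeR with total counts alone 639. In 20 simulations of unchanged strains against the same MA234.1 libraries the overlap was 0 as well. Because the 0 of the main fit follows from the missing ΔaslB calls, this comparison decides nothing about shared effects. The log2 fold changes of the deletions correlated at 0.86 across genes, against 0.02 in the simulations, and their covariance was 1.86 against 0.00. A covariance of 0.00 means that the simulations carried no error from the shared controls. They therefore set no baseline for the observed 0.86 and 1.86. Without ΔaslB replicate 2 the correlation was 0.92 and the covariance 3.25. Without that library, 2328 genes were higher and 2285 lower in both, where independent lists would share 770.2 and 781.9, and 5 went opposite ways. On an axis from the MA234.1 mean (0) to the ΔaslA mean (1), the library left out stood at 0.11. Replicates 1 and 3, which were kept, stood at 0.74 and 0.93, so the choice of library itself favours agreement with ΔaslA. The MA234.1 libraries were too few to split, and part of the excess over independent lists may come from the shared controls.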

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

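No gene list and no named gene met a criterion for closer inspection. Groups of 3 are too small for a test of single outlying samples. No list or named gene had all 3 ΔaslA libraries on 1 side of the MA234.1 mean and all 3 ΔaslB libraries on the other. This could hardly be met, since ΔaslB replicates 1 and 3 stood at 0.74 and 0.93 between the MA234.1 mean (0) and the ΔaslA mean (1). It therefore does not tell whether the deletions differ. Between the deletions edgeR called 0 genes, where 1633 had an unadjusted p under 0.05, DESeq2 called 517 and limma-voom 0.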

How the results depend on the processing

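Leaving out a library of the strain not compared, and testing lists in 6 libraries, were chosen after seeing the data. The count for ΔaslA against MA234.1 lay between 4148 and 6493 in the fits of all 9 or the 6 libraries, apart from 3847 with the fold threshold. The value of 6493 came from the 6 libraries alone. With 1 library left out it lay between 3008 and 5893, the higher values of 4963 to 5893 coming without a ΔaslB library. The main fit estimates each gene's spread over all 9 libraries, and ΔaslB was the widest group. The median SD of log2 CPM was 0.619 there, against 0.125 in MA234.1 and 0.254 in ΔaslA. The count and SEs of this comparison thus carry the spread of a strain it does not use. How much of the rise this explains was not tested. For ΔaslB against MA234.1 total counts alone gave 644 (median log2 fold change of all genes 0.102) and DESeq2 1741, and left-out libraries gave 0 to 5093. For ΔaslA against ΔaslB DESeq2 gave 517, and left-out libraries gave 0 to 1245. The overlap was 639 with total counts alone and 1668 with DESeq2, and 0 to 4613 with 1 library left out. The cause of the DESeq2 and total-count differences was not tested. The other alternatives gave 0 in these 3 results. At an unadjusted p under 0.05 the 9-library edgeR fit had 2926 and 1633 genes in the ΔaslB comparisons, and limma-voom, which also called 0, had 3305 and 1121. Called lists fell to 0 with an estimated correlation in each comparison, also when only the 6 libraries compared were fitted; with 1 library left out they numbered 14 each time for ΔaslA against MA234.1, 13 to 15 for ΔaslB against MA234.1 and 7 to 16 for ΔaslA against ΔaslB.

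With the replicate number as a block, edgeR called 4148, 0 and 0 genes, the overlap was 0, and 14, 15 and 14 lists were called. Deviations of same-numbered libraries correlated at -0.06 to 0.04 and those of other numbers at -0.04 to 0.06, so no pairing by number was seen. A shared effect that is small beside the differences between replicates could have been missed. Among 158 named results 0 reversed, 32 genes lost their call under at least 1 alternative, and 5 results, on the xlnR genes and the brlA gene ATCC64974_72370, became called under at least 1. A result with no adjusted p in an alternative was not counted there. With DESeq2, 110 of the 158 stayed the same, 4 became called and 0 lost their call, and the rest had no adjusted p. At these depths 3 counts correspond to 0.157 to 0.265 CPM, which limits what can be said of transcripts near 0 in ΔaslA.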

Other observations

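Gene ontology terms and the categories of the deposited annotation were tested after the data had been seen. In ΔaslA all 19 measured genes of rRNA processing rose (median log2 fold change 3.56), as did 26 of 31 aminoacyl-tRNA ligases, which charge tRNAs, and 12 of 15 genes of RNA polymerase activity, with 0 lower in each. Camera gave adjusted p = 2.14e-07, 8.53e-07 and 0.000376, and adjusted p = 0.645 with an estimated correlation for each. Of 97 monooxygenases 51 fell and 5 rose, and of 80 enzymes hydrolysing O-glycosyl bonds 43 fell and 5 rose (camera adjusted p = 1.37e-05 and 4.8e-06; adjusted p = 0.645 with an estimated correlation for both). Of 704 predicted secreted proteins 249 fell and 68 rose, and of 360 genes in secondary metabolism clusters 117 fell and 43 rose (camera adjusted p = 0.000552 and 0.00237; adjusted p = 0.301 with an estimated correlation for both).

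Some genes outside the naming rule were chosen after their values were seen. ATCC64974_22400, a gene for a fungal-specific transcription factor on contig 3, was at 0.216 CPM in the library labelled ΔaslB replicate 1, and at 50 and 22.6 CPM in replicates 2 and 3, 49.8 to 52.6 CPM in MA234.1 and 13.6 to 24.1 CPM in ΔaslA. Its neighbours ATCC64974_22370, ATCC64974_22380 and ATCC64974_22390 were also at least 4-fold below all other libraries there, at 81.5, 35.0 and 135 CPM. In that library 21 genes lay at least 4-fold above and 16 at least 4-fold below all 8 others, and in each other library 0 did. The hexose transporter gene KHT2 was at 961 CPM there against 43.9 to 120 CPM elsewhere. The named C2H2 zinc finger gene ATCC64974_80420, on contig 13, fell from 525 ± 14.4 CPM in MA234.1 to 0.783 ± 0.832 CPM in ΔaslA and was at 92.6, 321 and 42.6 CPM in ΔaslB replicates 1 to 3. Of 471 transcription factor genes, 2 with at least 10 CPM in MA234.1 were under 1% of that level in every ΔaslA library, ATCC64974_80420 and ATCC64974_87970, and 0 were in every ΔaslB library. Of the 377 genes that the authors' deposited table calls lower in ΔaslA than in ΔaslB, 330 drew the larger part of the summed ΔaslB CPM from replicate 2.

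The tests in the next paragraph on a label swap, a mixture and the culture were chosen only after the result was seen, while those on depth, gene length and other splits were not.

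The ΔaslB libraries lay apart from each other. On an axis from the MA234.1 mean (0) to the ΔaslA mean (1), over 4638 genes, they stood at 0.74, 0.11 and 0.93. A swap with another group needs a partner that correlates less with the rest of its group than the ΔaslB library does, and 0 of the 6 MA234.1 and ΔaslA libraries did so for replicates 1 and 2, but 1 did for replicate 3, ΔaslA replicate 2 (0.972 against 0.983), so that this swap stays open, as does a single wrong label; an earlier form of the test, by highest correlation, could not have seen it. A mixture of the 2 kinds of RNA may not account for replicate 1, in which 37 genes lay outside all other libraries, but stays open for replicates 2 and 3, where 0 did and where the median share of ΔaslA-like RNA implied by genes higher and by genes lower in ΔaslA differed by 0.208 (0.024 and 0.232) and 0.004 (0.987 and 0.991), against up to 0.066 in left-out libraries; with total counts alone replicate 2 differed by 0.083 against up to 0.052, under the bound of 2 times that value, and an earlier form of the test, the share of genes outside a widened range, did not decide (6.8% in replicate 1 against 10.4% in left-out ΔaslA replicate 2). A candidate explanation is that libraries came from cultures in different carbon or growth states, since acuE was at 62.3, 6300 and 29.2 CPM in replicates 1 to 3 and the ribosomal list at 2.29, 0.12 and 2.70 above MA234.1, but the 9 libraries share 1 protocol text that assigns no culture to a library, which keeps it open.

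For the difference between ΔaslA and MA234.1, thinning all libraries to the smallest total left 4602 called genes, against 4638, which argues against depth. Fold change and genomic span correlated at -0.054 (Spearman, across genes), which argues against a length bias as the whole cause. Among 10 splits of the 6 libraries the real one gave 6493 genes with edgeR and the highest other 0, so that 1 split gave as many; 10 splits are too few for a share under 0.05. For ΔaslB against MA234.1 and for ΔaslA against ΔaslB all 10 splits gave 0 with edgeR, the real ones with 2125 and 845 genes at an unadjusted p under 0.05 and limma-voom on 9 libraries also at 0, and they are likewise too few. The deletion itself, and a culture state that goes with it, stay open.

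The library ΔaslA replicate 2 stood apart from replicates 1 and 3, at -41.6 against 13.2 and 15.0 on the third principal component, which held 3.6% of the variance. Its greater depth may not account for this, since thinned to the smallest total of its group it correlated at 0.973 with replicate 1, as before thinning. Its deviation from the other replicates correlated with genomic span at -0.212 (Spearman, across genes), between the bounds set for and against a length bias. That explanation therefore cannot be told apart from others. The same value ran from -0.13 to 0.14 in the MA234.1 and ΔaslB libraries. In ΔaslA replicates 1 and 3 it was 0.155 and 0.209, but there it was taken against a mean that includes replicate 2. No biological explanation was tested.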
